A study of Mus musculus and Homo sapiens with 26 samples.

How the data were processed

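The samples were grouped by the submitters' labels alone, before the data were examined, and the comparisons, tests, gene lists and alternatives were fixed at that point. The mouse RNA files hold raw read counts per Ensembl gene (whole numbers, with no header, by the values of the deposited files). The human RNA files hold expected counts in the layout of RSEM gene output, per the file headers, beside TPM and FPKM columns by the authors that were not used here. Of the expected counts, 4.87% were not whole numbers, and all were rounded. The NKX2-2 ChIP table holds the authors' read counts at a common set of point positions, per the file header. The H3K27ac files hold the authors' peaks with a score, a signal value and the -log10 of p and of q for each peak, per the file headers and the narrowPeak layout. By the values, the deposited score is 10 times -log10 p without its decimals, and the lowest -log10 p is 1.00.

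STAR, with no version, and the builds mm10 and hg38 are named in the submitters' processing notes. The counter of the mouse files, the annotation versions, the ChIP aligner, the peak caller, its control libraries and the rule that chose the NKX2-2 sites are not given in the sources used here. RNA was extracted with a kit for fixed tissue (human) or a standard column kit (mouse), and the libraries were made from polyadenylated RNA, per the labels.

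Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and GenomicRanges 1.54.1, and figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. The mouse table held 39017 gene identifiers, of which 37607 had a symbol, and the human files held 60616. Counts per mouse RNA library, in the order of the replicate numbers, summed to 18490811, 17757991 and 24021440 (noDOX), 46840701, 21740964 and 25952651 (iWT), 16831996, 28255844 and 33099165 (iTN) and 17795653, 23613573 and 34853013 (iSD). Human libraries summed to 4117392 and 7296008 (pMN) and 3973425 and 6120000.0 (vpMN), and NKX2-2 libraries to 3986200 and 14957632 (iWT) and 8187844 and 6321041 (iTN). Genes were filtered with filterByExpr by group, scaled with TMM and tested with robust edgeR quasi-likelihood fits. This left 15592 mouse genes, 15366 human genes and 50051 of 50053 NKX2-2 sites, of which 1 shared its position with another. All 4 mouse RNA groups shared 1 fit with 6 contrasts. A gene or site was called at a Benjamini-Hochberg adjusted p below 0.05 with no fold threshold. Log2 ratios are given with the standard error of the fit, and CPM, reads scaled to the library total, as mean and SD over the libraries of a group.

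No sample was a copy of another. Between libraries of a group, chi-square per degree of freedom was at least 19.1 (mouse RNA), 24.1 (human RNA) and 7.03 (NKX2-2 table). In simulations with the libraries' depths and spread, the mouse test called 83% of genes changed 2-fold and 99% at 4-fold (2.15% of calls false). The human test called 1% and 53% (6.90% of calls false), and the site test 12% and 90% (4.67% false). The list test called 8 of 200 unchanged lists (unadjusted p below 0.05) and 20 of 20 shifted ones, which cannot judge co-regulated lists.

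The replicate numbers were checked for pairing, since the labels do not say what they mean. With group means removed, mouse RNA libraries with the same number correlated at 0.149 to 0.618 (median 0.472, 18 pairs). Those with different numbers did so at -0.465 to 0.0516 (median -0.224, 36 pairs). The pairing therefore comes from the data, and each mouse RNA contrast was also run with the number as an additive block. The paired fit called more genes in every mouse contrast (iSD against iWT 1715, unpaired 209), so failing the unpaired test does not show equality. H3K27ac shares were not compared within numbers.

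For the gene lists, 31 lists were fixed in advance and tested per contrast with camera on log2 CPM (prior count 2, preset correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over the 31 lists. Nkx2-2 was left out of every list. Alternatives were a correlation estimated per list, fry and the block. Human lists used the orthologs. The 2 sets of human genes higher or lower in vpMN were to be tested in the mouse contrasts with the same settings.

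The NKX2-2 bound genes were counted with a departure from the design. The gene table holds no strand, so a gene was bound when a site lay within 10 kb of either end of its span rather than of a start site, and the planned nearest start site became the nearest gene end. Changed genes were compared with all other tested genes that had a position by 8 two-sided Fisher exact tests, adjusted together. H3K27ac consensus peaks of a group were those held by both of its lists with at least 1 bp of overlap. The share of NKX2-2 sites inside a peak was computed per list, with no test between groups. A planned overlap of at least 50% of an NKX2-2 region could not be run, because the sites are points, and the alternatives for normalized values were void because the files hold counts.

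Fixed alternatives for counts were RLE size factors, upper quartile scaling, DESeq2, no count filter, a mean CPM of at least 1, the block and each library left out. They also included a test against a 1.5-fold change, only the compared groups in the fit, and table sums with no TMM factor. For sites and peaks they were sites above the median count, a distance of 50 kb, peaks with -log10 q of at least 5, the 20000 strongest peaks by the authors' signal value and reciprocal overlap of at least 50%. Chosen after seeing the data were 1 site per cluster within 1 kb, the site table without its 4 most read sites, and scaling to the sites with the fewest or the most reads. So were sites inside the gene, the 5000 most read sites, bound genes with the paired fit, comparison within 10 bins of mean expression, other settings for the human sets, and left-out libraries for lists, bound genes and peaks.

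The genes named were fixed by rule as Nkx2-2, 13 patterning and Notch genes and the members of each list with the smallest p. Added were up to 6 genes with the largest rise and 6 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and libraries that did not overlap. For the sites, the 5 largest losses and gains and the sites near the named genes were taken. No human gene was called, and the human genes named beyond the 13 and the list members were chosen after their values were seen, from a fit with the libraries divided by RNA class shares. TPM, FPKM, peak signal beyond ranking, genes without a position (bound genes only) and human entries of the pseudoautosomal Y copies were left out. Some genes that the rules would have named are not reported here.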

Results

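The series compared neural cultures around NKX2-2, a homeodomain transcription factor of the ventral spinal progenitor domain p3. Mouse A2lox.Cre embryonic stem cells were differentiated towards motor neurons and received doxycycline from day 3.5 for 24 h. It induced wild-type Nkx2-2 (iWT), a form with a mutated TN domain, the motif that binds Groucho/TLE corepressors (iTN), or a form with a mutated SD domain, an NK2-family motif (iSD). Uninduced cultures (noDOX) for RNA came only from the line carrying the wild-type transgene, so for iTN and iSD the line and doxycycline differ from noDOX together. Of the 2 noDOX libraries for H3K27ac, the first came from another line (HBG3). RNA was measured in 3 libraries of each of the 4 mouse groups, NKX2-2 binding in 2 libraries each of iWT and iTN, and H3K27 acetylation (H3K27ac, a mark of active promoters and enhancers) in 2 libraries each of noDOX, iWT and iTN. Human motor neuron organoids of the line NCRM1 were fixed on day 11 and sorted into OLIG2+ progenitors without (pMN) or with NKX2-2 (vpMN), with 2 RNA libraries each. Mouse RNA libraries held 16831996 to 46840701 counts, human ones 3973425 to 7296008 and NKX2-2 libraries 3986200 to 14957632. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples.

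Olig2, Pax6 and Neurog2 were strongly lower in iWT than in noDOX. Nkx2-2 rose from 9.18 ± 3.38 CPM in noDOX to 353 ± 19.6 CPM in iWT (n = 3 each; log2 5.26 ± 0.235, adjusted p = 3.43e-07). Olig2, which specifies motor neuron progenitors, fell from 252 ± 47.6 to 5.89 ± 4.04 CPM (-5.35 ± 0.504, adjusted p = 6.03e-05), and Pax6, which sets the dorsal limit of the p3 domain, fell from 117 ± 36.2 to 2.51 ± 0.271 CPM (-5.53 ± 0.342, adjusted p = 3.32e-06). Neurog2, a proneural factor of motor neuron progenitors, fell by 6.31 on the log2 scale (SE 0.505, adjusted p = 1.96e-05). In iWT, 940 genes were higher and 934 lower than in noDOX among 15592 tested (edgeR, adjusted p below 0.05), 480 and 224 of them by at least 2-fold.

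Other genes of the fixed set also changed in iWT. Irx3, a dorsal repressor of Olig2, fell (-2.34 ± 0.386, adjusted p = 0.00263), as did the motor neuron gene Mnx1 (-2.23 ± 0.287, adjusted p = 0.000499) and the progenitor gene Sox2 (-0.51 ± 0.0938, adjusted p = 0.00476). Nkx2-9, a p3 gene closely related to Nkx2-2, fell as well (-4.90 ± 0.383, adjusted p = 1.77e-05). Sim1, a marker of V3 neurons, rose from 0.237 to 1.08 CPM (2.24 ± 0.622, adjusted p = 0.0348), and the Notch ligand gene Dll1 rose (0.63 ± 0.157, adjusted p = 0.0225). The Sim1 call was lost without iWT replicate 1 (adjusted p = 0.134), 2 (0.0592) or 3 (0.0666) or noDOX replicate 1 (0.125) or 3 (0.108). The Dll1 call was lost without iWT replicate 1 (adjusted p = 0.111) or noDOX replicate 2 (0.0924) or 3 (0.0535). Nkx6-1, shared by the ventral progenitor domains (0.05 ± 0.235, adjusted p = 0.923), Isl1 (-0.42 ± 0.396, 0.555), Hes1 (0.15 ± 0.0952, 0.336) and Hes5 (0.27 ± 0.344, 0.679) did not pass the test.

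Among genes with a mean of at least 5 CPM in the higher group and no overlap between libraries, the largest rises in iWT besides Nkx2-2 were those of the uroplakin gene Upk3a (4.83 ± 0.894, adjusted p = 0.00499), the ion channel regulator Unc80 (3.87 ± 0.479, 0.000391), the cadherin gene Cdh22 (3.54 ± 0.328, 5.55e-05), Adamtsl2 (3.48 ± 0.312, 4.04e-05) and Phactr3 (3.13 ± 0.363, 0.000262). By the same rule, the largest falls beside Neurog2, Pax6 and Olig2 were those of the forkhead gene Foxb1 (-5.27 ± 0.303, adjusted p = 2.27e-06), the motor neuron gene Lhx4 (-5.14 ± 0.738, 0.00107) and Olig1 (-5.09 ± 0.424, 2.34e-05). With the samples paired, 4989 genes were called (2430 higher, 2559 lower), 1873 of the unpaired calls among them. Upper quartile scaling moved the division from 940 higher and 934 lower to 1136 and 719 (61.2% higher). The count fell to 1005 without noDOX replicate 1, 967 without noDOX replicate 2, 919 without iWT replicate 1 and 1182 without iWT replicate 3.

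**Figure D1:**
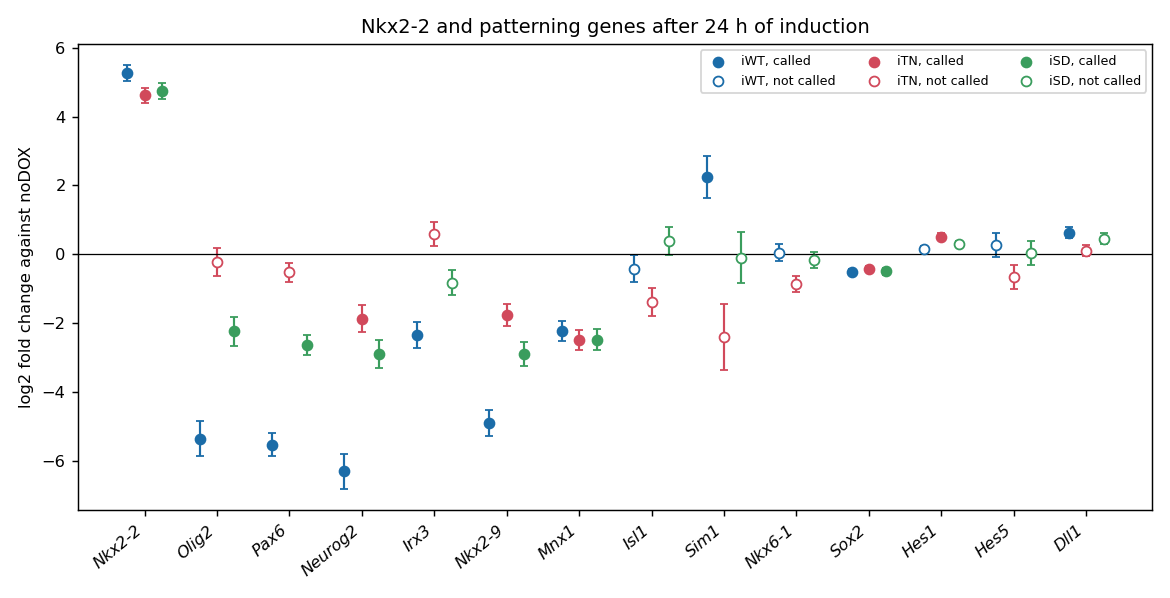
Log2 fold change against noDOX (vertical) of Nkx2-2 and 13 patterning and Notch genes (horizontal) in iWT, iTN and iSD; points are edgeR estimates with standard errors over 3 libraries per group, filled where called. Olig2 was at -5.35 in iWT, -0.24 in iTN and -2.24 in iSD.

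Of the 31 fixed lists, 12 were called in iWT against noDOX, 6 up and 6 down, and none of these calls was kept when the correlation was estimated per list. Of 8 measured pMN progenitor genes, 4 fell (Neurog2, Olig1, Olig2 and the LIM gene Lhx3, -4.85 ± 0.581) and 0 rose. For the pMN genes, 4 fell and 1 rose adjusted over the list alone (median -2.72, camera adjusted p = 0.0024; adjusted p = 0.17 with an estimated correlation). Of 16 motor neuron genes, 7 fell, Lhx3, Mnx1, Lhx4 and Chat (-2.80 ± 0.509), the acetylcholine synthesis gene, among them. As many, 7, fell adjusted over the list alone (median -0.43, adjusted p = 0.00713; adjusted p = 0.61 with an estimated correlation). Of 15 dorsal and intermediate progenitor determinants, 5 fell, led by Pax6, Sp8 (-3.08 ± 0.319) and Irx3. Of these determinants, 7 fell adjusted over the list alone (median -1.06, adjusted p = 0.003; adjusted p = 0.17 with an estimated correlation). The 8 measured p3 and V3 genes were divided, with 5 higher and 3 lower on either adjustment (5 and 3 adjusted over the list alone). Uncx (6.28 ± 0.527, adjusted p = 2.34e-05) and Slit1 (1.62 ± 0.261, 0.00225) rose and Nkx2-9 and Nkx2-1 (-3.68 ± 0.622, 0.00301) fell (list median 1.89, adjusted p = 0.285, not called).

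Genes of Hedgehog signalling and of the cell cycle fell in iWT. The pathway effector and target genes Gli1 (-3.00 ± 0.2, adjusted p = 5.42e-06), Gli2 (-3.84 ± 0.257, 5.42e-06) and Hhip (-1.65 ± 0.189, 0.000235) were among 7 of 15 measured Hedgehog genes that fell, with 0 higher. In the Hedgehog list, 7 fell and 1 rose adjusted over the list alone (median -0.41, adjusted p = 0.000136; adjusted p = 0.259 with an estimated correlation). Of 30 cell cycle genes, 9 fell, with cyclin D2 (Ccnd2, -1.39 ± 0.146) and the replication licensing genes Mcm6 (-0.60 ± 0.0811) and Mcm7 (-0.56 ± 0.0804) leading. In the cell cycle list, 12 fell adjusted over the list alone (median -0.28, adjusted p = 1.63e-08; adjusted p = 0.259 with an estimated correlation). The 7 CDK inhibitor genes were called up with 1 member higher, Cdkn1c (2.07 ± 0.167, adjusted p = 1.96e-05), and 1 adjusted over the list alone (median 0.34, adjusted p = 0.0362; adjusted p = 0.259 with an estimated correlation). Of 17 hypoxia and glycolysis genes, only the glucose transporter Slc2a1 fell (-1.41 ± 0.256, adjusted p = 0.00468), also 1 adjusted over the list alone (median -0.64, adjusted p = 0.0304; adjusted p = 0.762 with an estimated correlation).

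Neuronal commitment genes moved both ways in iWT. Of 26 proneural and commitment factors, 8 rose, with Insm1 (2.56 ± 0.244) and Neurod4 (1.60 ± 0.161) first, and 2 fell, Neurog2 the most. Among these factors, 9 rose and 3 fell adjusted over the list alone (median 0.32, adjusted p = 0.0345; adjusted p = 0.762 with an estimated correlation). Of 25 Notch genes, 5 rose, with Hey1 (1.82 ± 0.151), Mfng (0.96 ± 0.123) and Jag1 (0.82 ± 0.119) first, and 2 fell, Hey2 first (-1.23 ± 0.203). The Notch list had 9 higher and 2 lower adjusted over the list alone (median 0.23, adjusted p = 0.0304; adjusted p = 0.674 with an estimated correlation). Of 11 spinal interneuron genes, 5 rose, En1 of V1 interneurons first (3.08 ± 0.62), and 6 adjusted over the list alone (median 1.33, adjusted p = 0.00727; adjusted p = 0.38 with an estimated correlation). Of 12 floor plate genes, 2 rose and 4 did so adjusted over the list alone (median 0.45, adjusted p = 0.0345; adjusted p = 0.674 with an estimated correlation). Spon1, with the smallest p (1.35 ± 0.294, adjusted p = 0.0116), was no longer called without iWT replicate 1 (adjusted p = 0.0533). The 12 immediate early genes were called up with 0 members changed, also 0 adjusted over the list alone (median 0.41, adjusted p = 0.0345; adjusted p = 0.703 with an estimated correlation).

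The other 18 lists were not called in iWT. Visceral motor and serotonergic genes (3 of 9 higher and 2 lower, adjusted p = 0.263), pan-neuronal genes (4 of 28 higher, 0.168), and glial lineage genes (1 of 15 higher, 0.573) were among them. Neural progenitor genes (2 of 22 higher and 4 lower, 0.336) included the glutamate transporter Slc1a3 at -3.04 ± 0.179. So were Groucho and TLE corepressors (3 of 9 higher and 1 lower, 0.168), where Tle2 (3.03 ± 0.263) and Tle6 (3.10 ± 0.37) rose and Tle1 fell (-1.01 ± 0.113). Pancreatic endocrine genes (4 of 15 higher and 2 lower, adjusted p = 0.116), and Hox genes (1 of 24 higher and 1 lower, 0.381) did not pass. Nor did retinoid response (1 of 14 higher and 3 lower, 0.937), BMP and Wnt response (4 of 23 higher and 2 lower, 0.989) and p53 response (2 of 14 higher, 0.639). Stress response genes (1 of 16 higher and 4 lower, 0.168), the 5 histone genes (0 changed, 0.969) and the 7 mitochondrially encoded genes (0 changed, 0.979) were not called. Markers of other cell types did not pass either: pluripotent (1 of 12 higher, adjusted p = 0.846), mesoderm and somite (1 of 12 lower, 0.979), neural crest (1 of 9 higher, 0.168), endoderm (0 of 13, 0.989) and blood and endothelium (0 of 9, 0.989).

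With the TN domain mutated, Olig2 and Pax6 stayed near the noDOX level. Nkx2-2 reached 226 ± 35.9 CPM (log2 4.61 ± 0.229 against noDOX, n = 3, adjusted p = 1.23e-06). Olig2 was at 214 ± 32 CPM (-0.24 ± 0.409, adjusted p = 0.894) and Pax6 at 81.0 ± 3.26 CPM (-0.53 ± 0.269, adjusted p = 0.426). In the direct test of iTN against iWT, Olig2 (5.12 ± 0.499, adjusted p = 6.09e-05), Pax6 (5.001 ± 0.336, 8.5e-06), Neurog2 (4.44 ± 0.481, 0.000135), Irx3 (2.93 ± 0.391, 0.000653) and Nkx2-9 (3.15 ± 0.364, 0.000224) were higher. Nkx2-2 itself differed from iWT by -0.65 ± 0.192 (adjusted p = 0.0514), and passed with the samples paired (adjusted p = 0.0321).

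Against noDOX, 228 genes were higher and 185 lower in iTN (edgeR), 106 and 135 of them by at least 2-fold. Mnx1 fell to 2.59 ± 0.482 CPM (-2.48 ± 0.293, adjusted p = 0.000992). Neurog2 (-1.87 ± 0.392, adjusted p = 0.0254), Nkx2-9 (-1.76 ± 0.326, 0.0132) and Sox2 (-0.43 ± 0.0938, 0.0328) fell and Hes1, a Notch target, rose (0.51 ± 0.0954, 0.0132). By the rule used for iWT, the largest rises included the prokineticin receptor gene Prokr2 (4.02 ± 0.346, 0.000112), the muscle methyltransferase gene Smyd1 (3.99 ± 0.601, 0.0039), Rtl1 (2.68 ± 0.261, 0.000255) and Epha10 (2.58 ± 0.389, 0.0039). The largest falls by that rule included the somite gene Meox1 (-3.26 ± 0.477, 0.00338), vitronectin (Vtn, -3.12 ± 0.502, 0.00598), Shisa3 (-2.69 ± 0.331, 0.00119) and Syt6 (-2.44 ± 0.37, 0.00396). Nkx6-1 (-0.87 ± 0.237, adjusted p = 0.0828) passed with the samples paired (adjusted p = 8.62e-06). Irx3 (0.59 ± 0.358, 0.537), Isl1 (-1.39 ± 0.409, 0.108), Sim1 (-2.40 ± 0.966, 0.275), Hes5 (-0.66 ± 0.35, 0.449) and Dll1 (0.11 ± 0.157, 0.868) did not pass.

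Calls in iTN against noDOX depended on single libraries for several genes. That of Neurog2 was lost without iTN replicate 2 (adjusted p = 0.105) or 3 (0.0931) or noDOX replicate 1 (0.0839), 2 (0.0533) or 3 (0.0775). That of Nkx2-9 was lost without iTN replicate 1 (0.0598) or 3 (0.0593) or noDOX replicate 1 (0.0566), and Hes1 without iTN replicate 1 (0.0755) or noDOX replicate 1 (0.0668) or 2 (0.05). That of Sox2 was lost without iTN replicate 1 (0.0906) or 3 (0.125) or noDOX replicate 1 (0.122), 2 (0.07) or 3 (0.0892). The total of 413 genes became 1718 with the samples paired (918 higher, 800 lower) and 786 with DESeq2, and fell to 204 without noDOX replicate 1, 238 without noDOX replicate 3, 205, 231 and 225 without iTN replicates 1, 2 and 3.

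All 14 lists called in iTN against noDOX were lower, and none was kept with an estimated correlation. Of 26 proneural and commitment factors, 9 fell and 0 rose, among them Nhlh1 (-2.26 ± 0.191, adjusted p = 0.00011), Neurod4 (-1.63 ± 0.164, 0.000295), Ebf2 (-2.10 ± 0.214, 0.000331) and Hes6 (-0.81 ± 0.103, 0.00126). Across them, 17 fell and 1 rose adjusted over the list alone (median -0.83, adjusted p = 4.32e-12; adjusted p = 0.249 with an estimated correlation). Of 12 floor plate genes, 4 fell, Slit2 (-1.73 ± 0.257) and netrin 1 (Ntn1, -0.89 ± 0.157) first. As floor plate genes, 7 fell adjusted over the list alone (median -0.75, adjusted p = 7.24e-06; adjusted p = 0.249 with an estimated correlation). Of 16 motor neuron genes, 3 fell, Mnx1 first, and 10 fell and 2 rose adjusted over the list alone (median -1.20, adjusted p = 0.000881; adjusted p = 0.35 with an estimated correlation). Of 8 pMN progenitor genes, 2 fell, and 4 adjusted over the list alone (median -0.77, adjusted p = 0.000881; adjusted p = 0.245 with an estimated correlation). Of 8 p3 and V3 genes, 2 fell, Slit1 first (-1.64 ± 0.265), and 1 rose. Within the p3 list, 5 fell and 1 rose adjusted over the list alone (median -1.25, adjusted p = 0.00424; adjusted p = 0.249 with an estimated correlation). Of 9 visceral motor and serotonergic genes, 3 fell, Tbx20 (-2.42 ± 0.39) and Hand2 (-3.21 ± 0.524) first, and 1 rose. In this visceral list, 4 fell and 1 rose adjusted over the list alone (median -0.49, adjusted p = 0.00193; adjusted p = 0.249 with an estimated correlation).

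Of 28 pan-neuronal genes in iTN, 1 fell (Elavl4, -1.33 ± 0.218) and 1 rose (Syt1, 1.85 ± 0.247). These were 3 and 2 adjusted over the list alone (median -0.52, adjusted p = 0.0336; adjusted p = 0.657 with an estimated correlation). Of 30 cell cycle genes, 1 fell and 4 did so adjusted over the list alone (median -0.21, adjusted p = 2.97e-05; adjusted p = 0.249 with an estimated correlation). Of 15 Hedgehog genes, 0 were called and 1 fell adjusted over the list alone (median -0.13, adjusted p = 0.0336; adjusted p = 0.476 with an estimated correlation). Among lists of other tissues, mesoderm and somite genes fell with 4 of 12 members, Meox1 and Twist1 (-2.51 ± 0.408) first. Mesoderm members lower were 6 adjusted over the list alone (median -0.92, adjusted p = 0.00026; adjusted p = 0.249 with an estimated correlation). Pancreatic endocrine genes (1 of 15 lower, 4 adjusted over the list alone, adjusted p = 0.00028; adjusted p = 0.245 with an estimated correlation) were also lower. So were BMP and Wnt response genes (2 of 23, 3 adjusted over the list alone, Sfrp2 first at -1.71 ± 0.229, adjusted p = 0.00029; adjusted p = 0.369 with an estimated correlation). Endoderm genes (0 of 13 called, 2 lower adjusted over the list alone, median -1.39, adjusted p = 0.0016; adjusted p = 0.476 with an estimated correlation) were called down as a list. Pluripotent genes followed (0 of 12 called, 1 higher adjusted over the list alone, median -1.02, adjusted p = 0.0336; adjusted p = 0.517 with an estimated correlation). With the samples paired, the dorsal and intermediate determinants (adjusted p = 0.0417, 0.0545 unpaired) and the immediate early genes (adjusted p = 0.0417, 0.186 unpaired) were called as well.

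Compared directly, 756 genes were higher and 844 lower in iTN than in iWT (edgeR), 222 and 521 of them by at least 2-fold. By the rule used above, the genes highest in iTN included Fam69c (6.63 ± 0.456, adjusted p = 8.5e-06), the kinase gene Stk32a (4.65 ± 0.423, 3.63e-05) and Olig1 (4.43 ± 0.417, 4.63e-05). Phox2a, which specifies visceral motor neurons, was the lowest by that rule (53.6 ± 15.5 CPM in iWT, 1.27 ± 0.174 in iTN; -5.38 ± 0.504, adjusted p = 4.63e-05), followed by Fam163a (-4.57 ± 0.51, 0.000171), Hepacam2 (-4.55 ± 0.408, 3.5e-05), Shisa3 (-4.12 ± 0.34, 2.32e-05), Phactr3 (-3.51 ± 0.369, 0.000108) and Vtn (-3.51 ± 0.504, 0.00108). Nkx6-1 (-0.92 ± 0.237, adjusted p = 0.0287) was lower and Hes1 (0.36 ± 0.0947, 0.0311) higher in iTN. The Nkx6-1 call was lost without iTN replicate 1 (adjusted p = 0.0786) or 2 (0.107) or iWT replicate 1 (0.0879) or 3 (0.1). That of Hes1 was lost without iTN replicate 1 (0.139) or 2 (0.0763) or iWT replicate 1 (0.0529), 2 (0.118) or 3 (0.0814). Sim1 was lower in iTN (-4.64 ± 0.781, adjusted p = 0.00291), and Mnx1 (-0.25 ± 0.29, 0.644), Isl1 (-0.98 ± 0.405, 0.151) and Sox2 (0.08 ± 0.0936, 0.627) did not differ by the test. Dll1 (-0.52 ± 0.157, adjusted p = 0.0547) and Hes5 (-0.93 ± 0.348, 0.112) passed with the samples paired (adjusted p = 0.000455 and 0.00704). Paired, 4895 genes were called (2452 higher, 2443 lower), and upper quartile scaling moved the division from 756 higher and 844 lower to 583 and 990 (37.1% higher). The total of 1600 fell to 791 without iWT replicate 1, 955 without iWT replicate 3, 896 and 972 without iTN replicates 1 and 2.

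Several neuronal gene lists were lower in iTN than in iWT, but not the motor neuron list (3 of 16 higher and 1 lower, adjusted p = 0.491). Of 26 proneural and commitment factors, 17 were lower and 1 higher, with Neurod4 (-3.23 ± 0.172, adjusted p = 2.88e-06), Insm1 (-3.03 ± 0.249, 2.32e-05) and Hes6 (-1.23 ± 0.102, 2.46e-05) first. Of the factors, 19 were lower and 1 higher adjusted over the list alone (median -1.18, adjusted p = 7.57e-11; adjusted p = 0.3 with an estimated correlation). Of 28 pan-neuronal genes, 6 were lower and 1 higher, with Elavl4 (-1.87 ± 0.22), the neuronal tubulin Tubb3 (-1.90 ± 0.282) and Map2 (-1.86 ± 0.281) first. Pan-neuronal counts were 10 and 1 adjusted over the list alone (median -0.39, adjusted p = 0.00557; adjusted p = 0.603 with an estimated correlation). Of 12 floor plate genes, 8 were lower, Ntn1 (-1.34 ± 0.158) and Foxa2 (-1.25 ± 0.197) among them. Floor plate members lower were 9 adjusted over the list alone (median -1.29, adjusted p = 1.4e-07; adjusted p = 0.3 with an estimated correlation). Of 8 p3 and V3 genes, 4 were lower, Uncx (-7.14 ± 0.552) and Slit1 (-3.26 ± 0.279) first, and 1, Nkx2-9, higher. There, 5 were lower and 3 higher adjusted over the list alone (median -1.54, adjusted p = 0.0295; adjusted p = 0.3 with an estimated correlation). This list was not called with the samples paired (adjusted p = 0.131). Spinal interneuron genes (5 of 11 lower, 5 adjusted over the list alone, Bhlhe22 first at -3.38 ± 0.43, adjusted p = 0.000863; adjusted p = 0.3 with an estimated correlation) were also lower. So were visceral motor genes (4 of 9 lower, 5 adjusted over the list alone, Phox2a and Tbx20 first, adjusted p = 0.000863; adjusted p = 0.3 with an estimated correlation).

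Hedgehog genes were higher in iTN than in iWT, with 6 of 15 higher, Gli1 (2.95 ± 0.2, adjusted p = 8.5e-06) and Gli2 (3.60 ± 0.255, 8.5e-06) first, and 2 lower. Counts were the same adjusted over the list alone (median 0.14, adjusted p = 0.00277; adjusted p = 0.3 with an estimated correlation). Of 30 cell cycle genes, 4 were higher, Ccnd2 first (1.12 ± 0.145), and 5 adjusted over the list alone (median 0.15, adjusted p = 0.00277; adjusted p = 0.421 with an estimated correlation). Hypoxia and glycolysis genes were higher (2 of 17, 3 adjusted over the list alone, hexokinase 2, Hk2, first at 1.44 ± 0.265, list adjusted p = 0.00798; adjusted p = 0.584 with an estimated correlation). Pancreatic endocrine genes were lower (6 of 15 lower, 10 lower and 1 higher adjusted over the list alone, Insm1 and Chgb at -3.25 ± 0.36 first, adjusted p = 5.41e-05; adjusted p = 0.287 with an estimated correlation). BMP and Wnt response genes were lower (5 of 23 lower and 1 higher, 11 and 3 adjusted over the list alone, Wnt4 first at -2.32 ± 0.342, adjusted p = 0.00647; adjusted p = 0.493 with an estimated correlation). Immediate early genes were lower (3 of 12, 4 adjusted over the list alone, adjusted p = 0.00189; adjusted p = 0.424 with an estimated correlation). Markers of other tissues were lower too. Mesoderm genes were among them (2 of 12, 3 adjusted over the list alone, adjusted p = 0.000863; adjusted p = 0.3 with an estimated correlation), with neural crest genes (2 of 9, 2 adjusted over the list alone, Ngfr first at -2.46 ± 0.267, adjusted p = 0.0204; adjusted p = 0.3 with an estimated correlation). Endoderm genes were lower (1 of 13 lower and 1 higher, 6 and 1 adjusted over the list alone, adjusted p = 0.0105; adjusted p = 0.507 with an estimated correlation), as were pluripotent genes (1 of 12, 1 adjusted over the list alone, adjusted p = 0.0423; adjusted p = 0.507 with an estimated correlation). The pMN list (4 of 8 higher and 2 lower, median 1.12) was not called (adjusted p = 0.0839), and pairing added the Notch (adjusted p = 0.0483, 0.0626 unpaired) and Hox lists (adjusted p = 0.0291, 0.0663 unpaired).

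Pax6, Olig2, Neurog2 and Nkx2-9 fell less in iSD than in iWT. Nkx2-2 reached 245 ± 0.564 CPM (log2 4.73 ± 0.23 against noDOX, n = 3, adjusted p = 9.58e-07), with a difference of -0.53 ± 0.191 from iWT (adjusted p = 0.25) and 0.12 ± 0.191 from iTN (adjusted p = 0.845). Pax6 fell from 117 ± 36.2 to 18.8 ± 7.98 CPM (-2.64 ± 0.289, adjusted p = 0.000334) and Olig2 from 252 ± 47.6 to 53.5 ± 30.5 CPM (-2.24 ± 0.431, adjusted p = 0.0103). Both were higher than in iWT (Pax6 2.89 ± 0.321, adjusted p = 0.0017; Olig2 3.11 ± 0.465, adjusted p = 0.00818) and lower than in iTN (-2.11 ± 0.284, adjusted p = 0.00307; -2.003 ± 0.427, adjusted p = 0.0332). Olig2 lost its call against noDOX without iSD replicate 3 (adjusted p = 0.0546) and against iWT without iWT replicate 3 (0.0564), and against iTN without iSD replicate 2 (0.106) or 3 (0.132) or any of iTN replicates 1 (0.0871), 2 (0.0836) and 3 (0.0915).

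Against noDOX, 540 genes were higher and 482 lower in iSD (edgeR), 300 and 157 of them by at least 2-fold. Neurog2 (-2.90 ± 0.411, adjusted p = 0.00186), Mnx1 (-2.48 ± 0.293, 0.000533) and Nkx2-9 (-2.89 ± 0.343, 0.000533) fell, and so did Sox2 (-0.49 ± 0.0939, 0.00946), which lost its call without iSD replicate 2 (adjusted p = 0.0511). By the same rule the largest rises included the secretoglobin gene Scgb1a1 (6.97 ± 0.799, adjusted p = 0.00043), Upk3a (5.66 ± 0.903, 0.00363), Smyd1 (4.23 ± 0.602, 0.0019) and the phosphodiesterase gene Pde11a (4.10 ± 0.397, 0.000202). The largest falls included Tdh (-3.58 ± 0.7, 0.0113), the pepsinogen gene Pga5 (-3.54 ± 0.564, 0.00362), cubilin (Cubn, -3.14 ± 0.562, 0.00659) and Syt6 (-2.95 ± 0.382, 0.00092). Hes1 (0.30 ± 0.0953, adjusted p = 0.0818) and Dll1 (0.45 ± 0.157, 0.11) passed with the samples paired (adjusted p = 0.0191 and 0.00158). Irx3 (-0.83 ± 0.365, 0.203), Nkx6-1 (-0.16 ± 0.235, 0.742), Isl1 (0.39 ± 0.396, 0.623), Sim1 (-0.10 ± 0.741, 0.959) and Hes5 (0.02 ± 0.346, 0.978) did not pass. The total of 1022 became 3947 with the samples paired (1907 higher, 2040 lower), 1720 with DESeq2 and 441 with noDOX and iSD alone in the fit. It fell to 479 and 510 without noDOX replicates 1 and 2 and to 473 without iSD replicate 2.

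In iSD, 11 lists were called against noDOX, 2 up and 9 down, and none was kept with an estimated correlation. Cell cycle genes fell, 12 of 30, with Mcm6 (-0.56 ± 0.0811), Mcm7 (-0.53 ± 0.0804) and Ccnd2 (-0.93 ± 0.144) first. Cell cycle genes lower were 22 adjusted over the list alone (median -0.36, adjusted p = 2.18e-12; adjusted p = 0.14 with an estimated correlation). Of 15 Hedgehog genes, 6 fell, Gli1 (-2.03 ± 0.192) and Gli2 (-2.21 ± 0.235) first, and 7 adjusted over the list alone (median -0.59, adjusted p = 6.66e-05; adjusted p = 0.284 with an estimated correlation). Of 8 pMN genes, 5 fell, Olig1 first (-2.94 ± 0.372), also 5 adjusted over the list alone (median -1.79, adjusted p = 0.00159; adjusted p = 0.14 with an estimated correlation). Of 15 dorsal and intermediate determinants, 2 fell, Pax6 first, and 4 adjusted over the list alone (median -0.84, adjusted p = 0.00751; adjusted p = 0.14 with an estimated correlation). Of 28 pan-neuronal genes, 3 rose, Syt1 first (2.54 ± 0.249), and 4 adjusted over the list alone (median 0.50, adjusted p = 0.00028; adjusted p = 0.641 with an estimated correlation). Of 11 interneuron genes, 3 rose, Lhx5 first (2.59 ± 0.462), and 6 rose and 1 fell adjusted over the list alone (median 1.47, adjusted p = 0.0141; adjusted p = 0.464 with an estimated correlation). Proneural and commitment factors were not called (4 of 26 higher, with Insm1 at 1.95 ± 0.24 first, and 3 lower, adjusted p = 0.867), nor were p3 and V3 genes (2 of 8 higher, among them Uncx at 4.85 ± 0.553, and 3 lower).

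Stress response genes in iSD were lower (3 of 16, 5 adjusted over the list alone, Atf4 first at -0.58 ± 0.111, adjusted p = 0.000392; adjusted p = 0.453 with an estimated correlation). Hypoxia genes were lower too (1 of 17, 3 adjusted over the list alone, adjusted p = 0.000392; adjusted p = 0.641 with an estimated correlation). Among markers of other tissues, endoderm genes were lower (2 of 13 lower, 4 adjusted over the list alone, Sox17 first at -2.72 ± 0.54, adjusted p = 0.000508; adjusted p = 0.548 with an estimated correlation). Mesoderm genes (3 of 12, 6 adjusted over the list alone, adjusted p = 0.00751; adjusted p = 0.548 with an estimated correlation) and pluripotent genes (2 of 12 lower and 1 higher, 5 and 1 adjusted over the list alone, adjusted p = 0.02; adjusted p = 0.641 with an estimated correlation) were lower. With the samples paired, the mitochondrially encoded genes were called as well (adjusted p = 0.0484, 0.0774 unpaired).

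Between iSD and iWT, 124 genes were higher and 85 lower in iSD (edgeR), 69 and 66 by at least 2-fold. Neurog2 (3.41 ± 0.477, adjusted p = 0.00495), Foxb1 (3.36 ± 0.292, 0.000879), Stk32a (3.48 ± 0.406, 0.00229), Gnat3 (3.60 ± 0.479, 0.00385) and Gli2 (1.64 ± 0.25, 0.00973) were higher, and Hes6 (-0.67 ± 0.101, 0.00858) and Hepacam2 (-3.15 ± 0.367, 0.00229) lower. Nkx2-9 was higher (2.01 ± 0.36, adjusted p = 0.0187), though not without iSD replicate 3 (adjusted p = 0.0657) or iWT replicate 3 (0.0746). Mnx1 (-0.24 ± 0.289, adjusted p = 0.836), Sox2 (0.02 ± 0.0936, 0.975) and Irx3 (1.51 ± 0.382, 0.0787) did not pass, and Sim1 (-2.35 ± 0.598, 0.0809) passed with the samples paired (adjusted p = 0.0181). The total of 209 became 1715 with the samples paired (772 higher, 943 lower), 620 with DESeq2 and 69 with the 2 groups alone in the fit. It fell to 68, 124 and 75 without iWT replicates 1, 2 and 3 and to 121 and 90 without iSD replicates 1 and 3.

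Of the 31 lists, 13 were called in iSD against iWT, none of them with an estimated correlation. Of 26 proneural and commitment factors, 4 were lower and 1 (Neurog2) higher, and 10 and 3 adjusted over the list alone (median -0.33, adjusted p = 0.0144; adjusted p = 0.644 with an estimated correlation). Of 8 pMN genes, 3 were higher, and 4 were higher and 1 lower adjusted over the list alone (median 1.15, adjusted p = 0.0145; adjusted p = 0.45 with an estimated correlation), a call lost with the samples paired (adjusted p = 0.0509). Of 12 floor plate genes, 1 was lower and 4 adjusted over the list alone (median -0.42, adjusted p = 0.000195; adjusted p = 0.45 with an estimated correlation). Of 16 motor neuron genes, 1 was higher, and 3 higher and 1 lower adjusted over the list alone (median 0.55, adjusted p = 0.00793; adjusted p = 0.485 with an estimated correlation). Of 28 pan-neuronal genes, 0 were called and 4 were higher adjusted over the list alone (median 0.29, adjusted p = 0.0144; adjusted p = 0.71 with an estimated correlation). Endoderm (0 of 13 called, 8 lower adjusted over the list alone, adjusted p = 3.47e-05), mesoderm (0 of 12, 1 lower, 0.000195), immediate early (0 of 12, 3 lower, 0.000195) and pluripotent genes (0 of 12, 4 lower, 0.000999) were lower as lists (adjusted p = 0.45 with an estimated correlation for each). BMP and Wnt response genes (1 of 23 higher and 2 lower, 2 and 3 adjusted over the list alone, median -0.37) were lower with adjusted p = 0.0144 (adjusted p = 0.502 with an estimated correlation). Stress response genes (0 of 16, 2 lower adjusted over the list alone) were lower with adjusted p = 0.0484 (adjusted p = 0.503 with an estimated correlation). The histone genes (0 of 5, also 0 adjusted over the list alone, median -0.34) were lower with adjusted p = 0.0268 (adjusted p = 0.45 with an estimated correlation). The mitochondrially encoded genes (0 of 7, also 0 adjusted over the list alone, median 0.25) were higher with adjusted p = 0.04 (adjusted p = 0.553 with an estimated correlation).

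Between iSD and iTN, whose Nkx2-2 levels did not differ by the test, 192 genes were higher and 107 lower in iSD (edgeR), 127 and 42 by at least 2-fold. Uncx (5.70 ± 0.579, adjusted p = 0.000479), Phox2a (3.61 ± 0.487, 0.00307), Bhlhe22 (3.35 ± 0.431, 0.00274), Neurod4 (2.41 ± 0.167, 6.53e-05), Insm1 (2.43 ± 0.244, 0.000479) and St18 (2.56 ± 0.262, 0.000479) were higher in iSD. Olig1 (-2.27 ± 0.366, 0.00736), Gli1 (-1.98 ± 0.192, 0.000479), Gli2 (-1.96 ± 0.234, 0.00161) and Slc1a3 (-1.71 ± 0.17, 0.000479) were lower. Isl1 was higher (1.78 ± 0.411, adjusted p = 0.0487), though not without iSD replicate 1 (0.0759), 2 (0.163) or 3 (0.0644) or iTN replicate 2 (0.197) or 3 (0.149). Neurog2 (-1.03 ± 0.395, adjusted p = 0.234), Nkx2-9 (-1.13 ± 0.331, 0.114), Nkx6-1 (0.71 ± 0.237, 0.166) and Dll1 (0.34 ± 0.157, 0.334) passed with the samples paired (adjusted p = 0.024, 0.0499, 5.48e-05 and 0.0144). The total of 299 became 2216 with the samples paired (1066 higher, 1150 lower), 793 with DESeq2 and 176 with the 2 groups alone in the fit. It fell to 186, 124 and 140 without iTN replicates 1, 2 and 3 and to 138 without iSD replicate 2.

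Of the 31 lists, 13 were called in iSD against iTN, 9 up and 4 down, none with an estimated correlation. Proneural and commitment factors were higher (8 of 26, and 18 higher and 2 lower adjusted over the list alone, median 0.83, adjusted p = 3.28e-14; adjusted p = 0.255 with an estimated correlation). Pan-neuronal genes were higher as well (5 of 28, 14 adjusted over the list alone, Elavl4 first at 1.39 ± 0.218, list median 0.93, adjusted p = 3.36e-11; adjusted p = 0.34 with an estimated correlation). Floor plate genes were higher (1 of 12, 6 adjusted over the list alone, adjusted p = 3.69e-05; adjusted p = 0.289 with an estimated correlation), and interneuron genes too (2 of 11, 5 adjusted over the list alone, adjusted p = 0.000296; adjusted p = 0.255 with an estimated correlation). Visceral motor genes (3 of 9, 4 adjusted over the list alone, adjusted p = 0.000296; adjusted p = 0.255 with an estimated correlation) and Notch genes (4 of 25, 6 adjusted over the list alone, Hey1 first at 1.79 ± 0.152, adjusted p = 0.00337; adjusted p = 0.353 with an estimated correlation) were higher. Pancreatic endocrine genes (4 of 15, 5 adjusted over the list alone, Chgb at 2.26 ± 0.353 among them) were higher with adjusted p = 2.59e-05 (adjusted p = 0.255 with an estimated correlation). Groucho and TLE corepressors (2 of 9, 2 adjusted over the list alone, Tle2 first at 1.62 ± 0.246) were higher with adjusted p = 0.0461 (adjusted p = 0.255 with an estimated correlation). Stress response genes (0 of 16, also 0 adjusted over the list alone) were lower with adjusted p = 0.0028 (adjusted p = 0.353 with an estimated correlation). Cell cycle genes were lower (2 of 30, 8 adjusted over the list alone, adjusted p = 1.74e-06; adjusted p = 0.255 with an estimated correlation). So were Hedgehog genes (4 of 15, 7 adjusted over the list alone, adjusted p = 0.00101; adjusted p = 0.289 with an estimated correlation) and hypoxia and glycolysis genes (1 of 17, 8 adjusted over the list alone, Hk2 at -1.65 ± 0.267, list adjusted p = 3.61e-06; adjusted p = 0.365 with an estimated correlation). The p3 and V3 list (3 of 8 higher, 4 higher and 2 lower adjusted over the list alone, adjusted p = 0.0448; adjusted p = 0.289 with an estimated correlation) was not called with the samples paired (adjusted p = 0.193), where the Hox list was (adjusted p = 0.043, 0.172 unpaired).

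**Figure D2:**
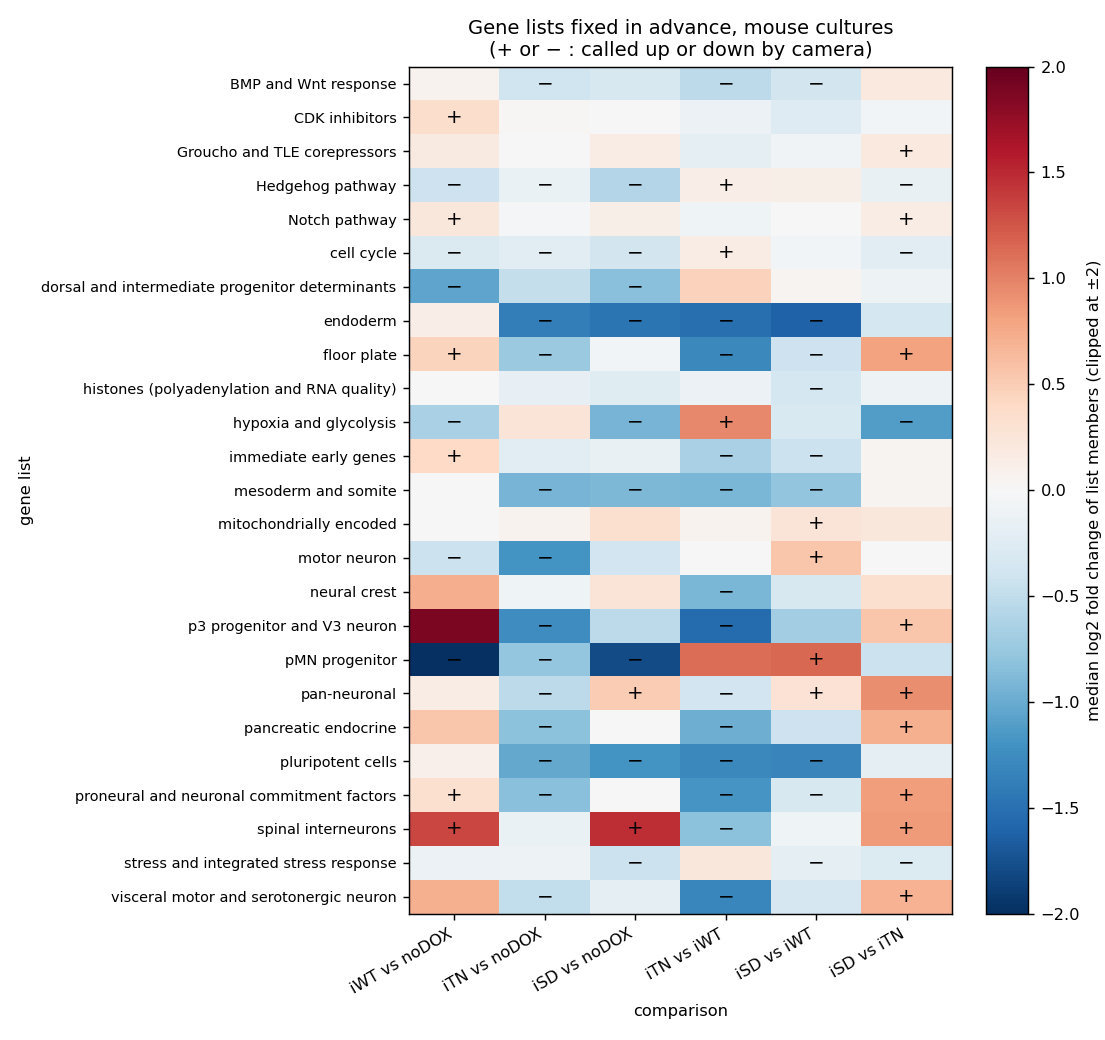
Median log2 fold change of the members of each gene list (color, vertical) in 6 mouse comparisons (horizontal), with + or - where camera called the list. The proneural and commitment list had medians of -0.83 in iTN against noDOX and 0.83 in iSD against iTN.

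The genes called in iWT against noDOX were followed into the mutants. Of the 940 genes higher in iWT than in noDOX, 105 were also called higher in iTN and 355 in iSD, and their median log2 change was 1.01 in iWT, 0.27 in iTN and 0.62 in iSD. Of the 934 lower genes, 63 were called lower in iTN and 343 in iSD, with medians of -0.54 in iWT, -0.14 in iTN and -0.39 in iSD. In direct unpaired tests, 441 of the higher genes differed between iTN and iWT and 62 between iSD and iWT. Of the lower genes, 422 and 75 did. The direct tests share the iWT libraries with the choice of these genes, which favors such differences. The contrasts against noDOX share its libraries, which alone gave correlations of 0.537 for iWT with iTN or iSD in simulated data with no effect, against 0.351 observed with iTN and 0.669 with iSD. The simulated covariance was 0.0554 and the observed 0.112 and 0.238 (0.0565 and 0.183 more), which library pairing may also shape.

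Independent lists would have shared 13.7 genes higher and 11.1 lower between iWT and iTN (105 and 63 observed), 32.6 and 28.9 between iWT and iSD (355 and 343 observed) and 7.90 and 5.72 between iTN and iSD (139 and 82 observed). The 10 simulations held no effect, so their 0 shared calls decide nothing. The 3 control libraries cannot be divided into sets of at least 2, so shared controls may give part of the excess.

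**Figure D3:**
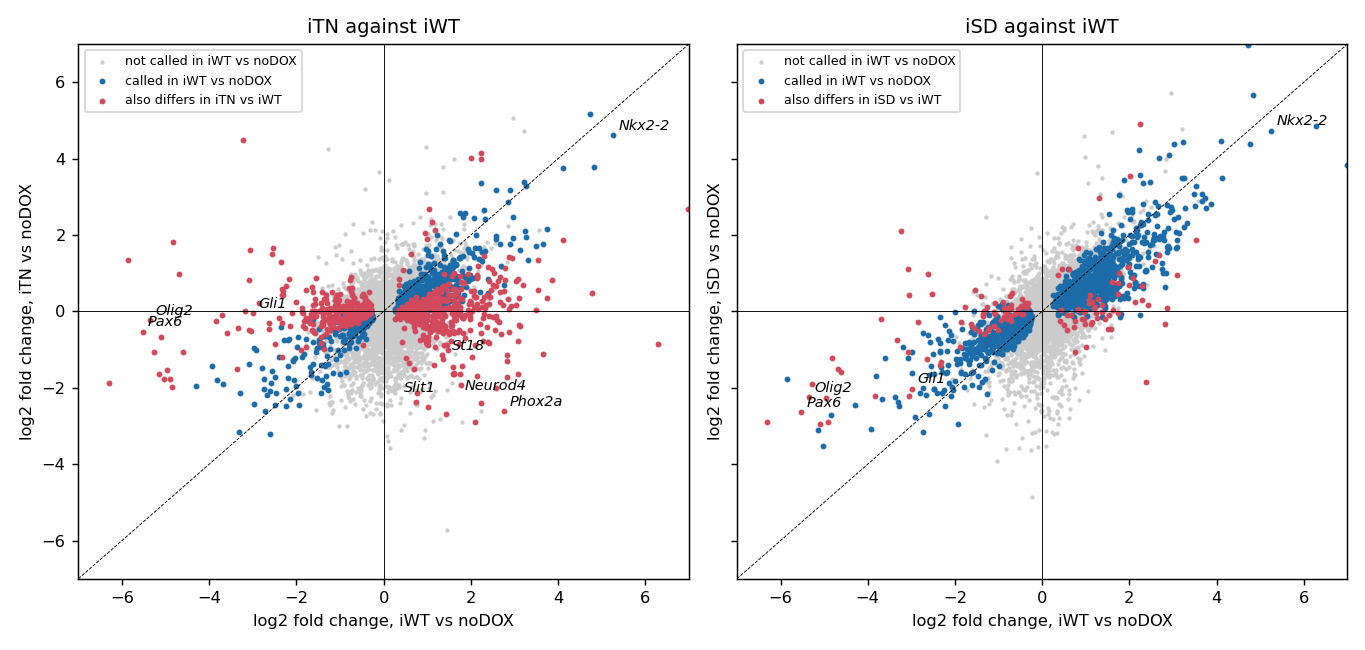
Log2 fold change against noDOX in iTN (left) or iSD (right) against that in iWT, each point a gene, 3 libraries per group, colored where called in iWT and where the mutant also differed from iWT. Neurod4 lay at 1.60 in iWT and -1.63 in iTN, and Olig2 at -5.35 and -0.24.

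In the human organoids, no gene was called between vpMN and pMN progenitors (0 of 15366 by edgeR with n = 2 each, 274 at an unadjusted p below 0.05), while DESeq2 called 31, all lower in vpMN. NKX2-2, 1 of the proteins sorted on, was at 50.8 ± 13.9 CPM in vpMN and 10.46 ± 10.6 CPM in pMN (log2 2.23 ± 0.724, edgeR adjusted p = 1), and NKX2-8, a gene related to NKX2-2, at 39.8 ± 42.8 and 4.42 ± 6.25 CPM (3.07 ± 1.38, adjusted p = 1). OLIG2, the other protein of the sort, was at 274 ± 77.0 and 235 ± 19.8 CPM (0.22 ± 0.264, adjusted p = 1), PAX6 at 179 ± 18.8 and 217 ± 32.9 CPM (-0.28 ± 0.229, 1) and SOX2 at 358 ± 51.5 and 208 ± 54.6 CPM (0.78 ± 0.267, 1). The libraries of either number differed in their RNA classes: the share of RN7SL1 and RN7SL2 was 0.808% and 0.759% in the libraries numbered 1 and 2.91% and 2.84% in those numbered 2, and that of mitochondrially encoded genes 5.40% and 5.25% against 2.67% and 2.65%. Within these libraries, the log2 ratio of vpMN over pMN was 3.62 and 1.74 for NKX2-2 and 2.94 for NKX2-8 in those numbered 2 (the pMN library numbered 1 had 0 NKX2-8 counts). A fit with the libraries divided in this way, by their numbers, called 63 genes, 3 higher and 60 lower in vpMN. With no count filter the edgeR fit called 58 genes (3 higher, 55 lower). Fits without 1 library left only 1 in a group, and the lean towards lower genes was not kept without pMN replicate 2.

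Neuronal genes had lower values in vpMN. After the values were seen, genes called in that fit with the libraries divided were named. ST18 was the first (9.55 ± 3.26 CPM in vpMN, 109 ± 34.4 in pMN; -3.53 ± 0.39, edgeR adjusted p = 0.464, and 0.000309 within the divided libraries). EBF3 (-2.74 ± 0.358, adjusted p = 0.464, within 0.000752), INSM1 (-3.10 ± 0.498, 0.591), LHX4 (-2.94 ± 0.486, 0.591), NEUROD1 (-2.74 ± 0.559, 1) and EBF2 (-2.76 ± 0.502, 0.77), all transcription factors of neurons, were named too. The retinoid binding protein gene CRABP1 (-2.67 ± 0.779, 1), CHRNA3 (-2.91 ± 0.604, 1), P2RX3 (-2.78 ± 0.462, 0.591), SPNS2 (-3.05 ± 0.426, 0.549) and DLL4 (-2.39 ± 0.618, 1) followed. The mitotic gene ASPM (0.84 ± 0.259, adjusted p = 1) and the cadherin gene CDH6 (0.88 ± 0.434, 1) had higher values in vpMN. NEUROG2 was at 128 ± 46.7 CPM in vpMN and 238 ± 86.2 in pMN (-0.89 ± 0.363, adjusted p = 1, within 0.0191), and DLL1 at 121 ± 9.09 and 215 ± 14.2 (-0.83 ± 0.214, 1, within 0.0414). NKX2-8 also passed within the divided libraries (adjusted p = 0.0283), and NKX2-2 did not (0.0523). MNX1 was at 1.14 ± 0.888 and 12.9 ± 2.15 (-3.41 ± 0.774, 1, within 0.117) and ISL1 at 0.242 ± 0.342 and 6.89 ± 6.48 (-4.52 ± 1.49, 1, within 0.592). NKX6-1 (0.27 ± 0.219, adjusted p = 1), IRX3 (-1.10 ± 1.16, 1), HES1 (0.44 ± 0.302, 1) and HES5 (0.11 ± 0.558, 1) did not pass in either fit.

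**Figure D4:**
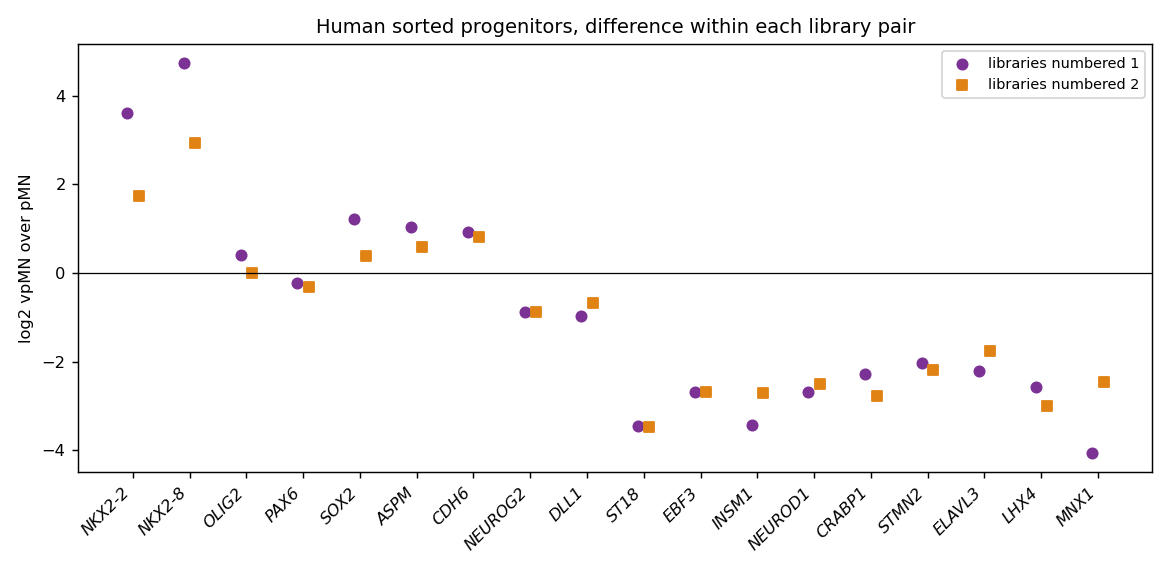
Log2 ratio of vpMN over pMN (vertical) for 18 human genes (horizontal), 1 point for each of the 2 pairs of libraries with the same number. NKX2-2 lay at 3.62 and 1.74 and NEUROG2 at -0.89 in both.

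Of the 31 lists, 5 were called in human cells (11 within the divided libraries), with 0 members called singly, and none was kept with an estimated correlation. Proneural and commitment factors were lower (25 measured, 10 lower adjusted over the list alone, median -1.57, adjusted p = 6.22e-22; adjusted p = 0.391 with an estimated correlation), with ST18, EBF3 and INSM1 first. Pan-neuronal genes were lower (27 measured, 12 lower adjusted over the list alone, STMN2 at -2.13 ± 0.27 and ELAVL3 at -2.02 ± 0.308 first, list median -1.18, adjusted p = 2.35e-21; adjusted p = 0.254 with an estimated correlation). Motor neuron genes were lower (10 measured, 6 lower adjusted over the list alone, ONECUT2 at -1.88 ± 0.244 first, list median -1.59, adjusted p = 4.97e-10; adjusted p = 0.318 with an estimated correlation). Pancreatic endocrine genes, a list that holds INSM1 and NEUROD1, were lower (9 measured, 4 lower adjusted over the list alone, median -2.01, adjusted p = 0.000234; adjusted p = 0.391 with an estimated correlation). Cell cycle genes were higher (30 measured, 0 adjusted over the list alone, PLK1 at 0.74 ± 0.242 first, list median 0.40, adjusted p = 6.67e-08; adjusted p = 0.564 with an estimated correlation).

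The planned test of vpMN genes in the mouse contrasts had empty sets, because no human gene was called. With the 200 human genes of smallest p per direction instead, 10 of 12 camera tests were called and none was kept with an estimated correlation. Genes with lower values in vpMN were lower in iTN than in iWT (11 higher, 48 lower, median -0.36, adjusted p = 7.56e-07; adjusted p = 0.43 with an estimated correlation). They were higher in iSD than in iTN (25 higher, 1 lower, median 0.37, adjusted p = 2.56e-12; adjusted p = 0.326 with an estimated correlation). Against noDOX they were higher in iWT (median 0.17, adjusted p = 0.0352; adjusted p = 0.675 with an estimated correlation, and 0.139 with sets from the divided libraries) and lower in iTN (median -0.23, adjusted p = 2.51e-05; adjusted p = 0.482 with an estimated correlation). Genes with higher values in vpMN were lower in iWT (median -0.16, adjusted p = 3.38e-05; adjusted p = 0.176 with an estimated correlation) and iSD (median -0.21, adjusted p = 2.75e-07; adjusted p = 0.139 with an estimated correlation) than in noDOX.

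NKX2-2 binding differed between iTN and iWT in both directions. Of 50051 tested sites, 7042 had more and 8151 fewer reads in iTN (edgeR, n = 2 each), 5559 and 7144 of them by at least 2-fold. Distances are to the nearest gene end, even for sites inside a gene. The largest losses were on mm10 chromosome 3 at 53410542 (-4.13 ± 0.408, adjusted p = 9.2e-20, 41.5 kb from Nhlrc3), with its neighbor at 53410595. Then came chromosome 2 at 62734037 (-3.84 ± 0.403, 39.9 kb from Gca) and 3 at 25730578 (-3.84 ± 0.39, 309 kb from Nlgn1). Next were chromosome 15 at 25392172 (-3.81 ± 0.39, 21.6 kb from Basp1) and 7 at 111654871 (-3.78 ± 0.405, 125 kb from Galnt18). The largest gains were on chromosome 13 at 12402997 (3.72 ± 0.393, 7.62 kb from Heatr1) and 5 at 49880444 (3.70 ± 0.442, 79.5 kb from Adgra3). Chromosomes 4 at 104085682 (3.68 ± 0.393, 466 kb from Dab1), 7 at 49361732 (3.50 ± 0.462, 248 kb from Nav2) and 2 at 66928158 (3.49 ± 0.388, 143 kb from Scn7a) followed.

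Near the patterning genes, 4 of 5 sites within 10 kb of Neurog2 gained reads in iTN, 3 of them within 1 kb of each other (the largest 2.23 ± 0.38, adjusted p = 1.82e-07), as did the only site near Isl1 (2.83 ± 0.429, 3.54e-09). The only sites near Mnx1 (-1.33 ± 0.364, adjusted p = 0.00196) and Nkx2-9 (-1.20 ± 0.351, 0.00403) lost reads, as did 1 of 4 near Pax6 (-1.20 ± 0.458, 0.033) and 1 of 2 near Nkx2-2 (-0.97 ± 0.368, 0.0314). Of 7 sites near Dll1, 1 lost reads (-2.25 ± 0.357, adjusted p = 2.02e-08) and 2 gained them, and of 6 near Hes1, 1 gained reads (0.93 ± 0.339, 0.0256). No site near Irx3, Nkx6-1, Sox2 or Hes5 was called. Without iWT replicate 2, the calls near Nkx2-9 (adjusted p = 0.284), Pax6 (0.178), Nkx2-2 (0.436) and Hes1 (0.27) and those of the gains near Dll1 (0.172 and 0.0868) were lost. Leaving out iTN replicate 1 ended those of Nkx2-9 (0.0889), Pax6 (0.469), Nkx2-2 (0.312) and 1 gain near Dll1 (0.0628), and leaving out iTN replicate 2 those of Nkx2-9 (0.0767), Pax6 (0.274), Nkx2-2 (0.186) and Hes1 (0.151). The calls near Pax6 (0.1) and Nkx2-2 (0.139) were also lost with scaling to the sites with the fewest reads. No site lay within 10 kb of Olig2. Scaling to the sites with the fewest reads moved the division from 7042 higher and 8151 lower (46.4% higher) to 8758 and 5948 (59.6% higher). The count fell to 6369 without iWT replicate 2 and to 9671 without iTN replicate 1, against 15193 with all libraries.

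Genes that changed had an NKX2-2 site nearby more often than other genes. Of 15017 tested genes with a position, 8127 (54.1%) had a site within 10 kb of an end. A site was near 63.4% of the genes lower in iWT than in noDOX against 53.5% of the others (odds ratio 1.5, 95% interval 1.31 to 1.73, Fisher exact adjusted p = 1.16e-08), and near 60.0% of the higher genes against 53.7% (1.29, 1.12 to 1.48, adjusted p = 0.000313). All 8 tests of the family were called. In iTN against noDOX a site was near 69.0% of higher genes (1.91, exact adjusted p = 1.13e-05) and 66.1% of lower genes (1.66, 0.00114). For iSD it was 68.5% of higher (1.88, 3.3e-11) and 58.8% of lower genes (1.22, 0.0363), and in iTN against iWT 68.6% of higher (1.91, 1.08e-15) and 60.5% of lower genes (1.32, 0.000235). Several calls were lost with other rules. That of genes lower in iSD was lost within 10 bins of mean expression (1.16, adjusted p = 0.125), with sites above the median count (1.22, 0.0596), with sites inside genes added (1.11, 0.289) and with genes of the paired fit (0.983, 0.737). It was also lost without iSD replicate 2 (1.26, exact adjusted p = 0.132) or noDOX replicate 2 (1.24, 0.112). That of genes higher in iWT was lost with sites above the median count (1.15, 0.0596) and with the 5000 most read sites (0.896, 0.615). Genes lower in iTN than in iWT lost it with the same sites (1.09, 0.248; 1.10, 0.615), and that of genes lower in iTN than in noDOX with a distance of 50 kb (1.69, 0.101).

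H3K27ac near genes with lower RNA in iWT than in noDOX was less frequent in iWT than in noDOX and iTN. Of the NKX2-2 sites near those genes, 29.1 ± 1.05% lay in an H3K27ac peak in noDOX, 19.0 ± 0.0658% in iWT and 32 ± 2.96% in iTN (mean and SD of n = 2 lists each, peaks by the authors). With peaks of -log10 q of at least 5 these shares were 17.6%, 6.24% and 12.4%, and with the 20000 strongest peaks 22.3%, 10.6% and 19.5%. Near genes higher in iWT they were 24.2 ± 4.75%, 30.4 ± 2.07% and 32.7 ± 3.14%, and near genes not called 24.7%, 22.3% and 31.5%. With the q limit, shares near higher genes were 9.71%, 9.65% and 9.22% and near genes not called 12.7%, 7.69% and 11.2%. The strongest peaks gave 16.1%, 21% and 18.7% near higher genes and 17%, 13.4% and 17.7% near genes not called. Sites with more reads in iTN lay in peaks more often (32.1 ± 1.57% in noDOX, 21.7 ± 2.46% in iWT and 39.0 ± 1.41% in iTN) than sites with fewer reads in iTN (6.85 ± 0.226%, 10.1 ± 0.121% and 9.56 ± 2.19%). The q limit gave 12.2%, 5.48% and 10.7% against 0.626%, 0.669% and 0.245%, and the strongest peaks 20.1%, 11.5% and 22% against 2.18%, 4.07% and 1.27%. Over all sites the shares were 16.7 ± 0.93%, 14.5 ± 0.89% and 21.9 ± 1.35%, and 3.58 to 6.34% when the sites were shifted. The excess of iTN over noDOX did not hold with the q limit (4.14% against 5.07%) and was small with the strongest peaks (9.15% against 9.01%). No test between groups was made.

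**Figure D5:**
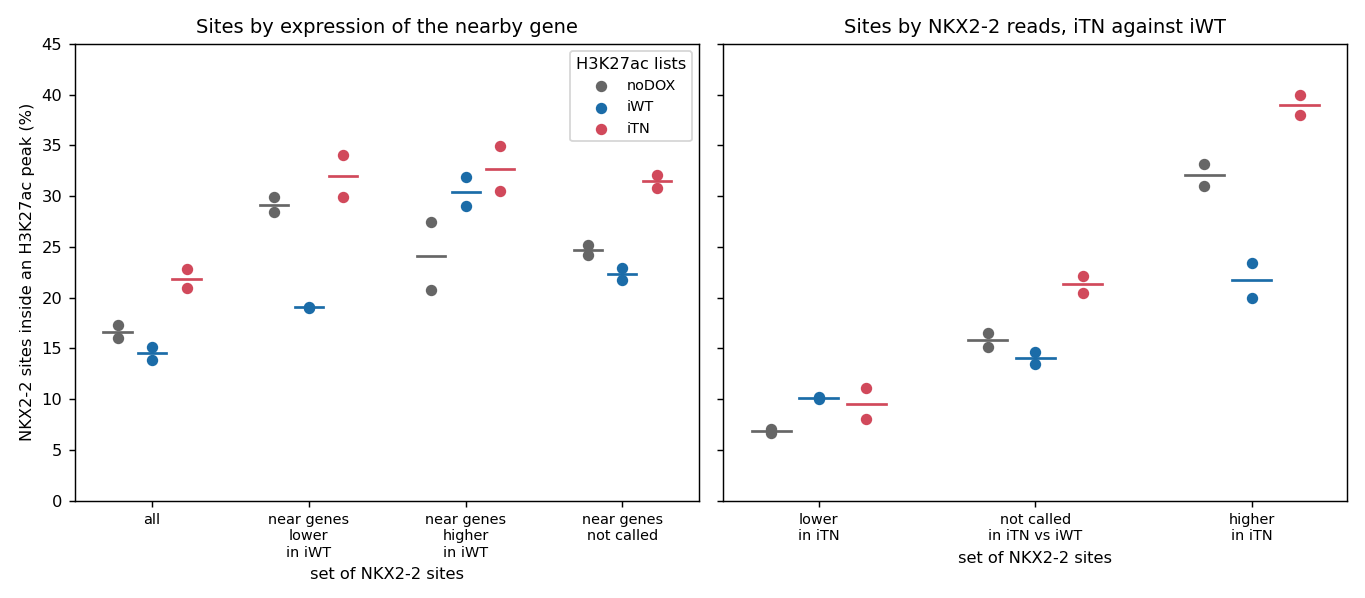
Percentage of NKX2-2 sites inside an H3K27ac peak (vertical) for sets of sites (horizontal), each point a list, bars the mean of 2 lists per group. Near genes lower in iWT the means were 29.1% in noDOX, 19.0% in iWT and 32% in iTN.

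Peaks were searched only at genes named by rule, many for large RNA changes, which favors agreement with RNA. Inside or within 10 kb of Pax6, Olig2, Nkx2-9, Foxb1 and Fam69c, all noDOX and iTN lists held peaks and no iWT list did. The RNA of all 5 fell in iWT. With the 20000 strongest peaks per list this peak pattern held for Pax6, Nkx2-9, Foxb1, Fam69c and Irx3. With -log10 q of at least 5 (5273 to 10530 peaks per list) it held for Pax6, Fam69c, Stk32a and Srgn. Stk32a and Srgn had peaks in iWT without a limit, and Srgn RNA did not fall there (0.19 ± 0.582, adjusted p = 0.881). The lists held 133509 and 92277 peaks in noDOX, 101774 and 170946 in iWT and 213765 and 288036 in iTN, and 48986, 53440 and 86140 were held by both lists of a group. Of these shared noDOX peaks, 58.7% overlapped a shared peak of iWT and 68.8% one of iTN. Of those of iWT, 56.7% overlapped noDOX and 65.7% iTN, and of those of iTN, 44.1% noDOX and 42.8% iWT. The Jaccard index between 2 lists averaged 0.320 within groups (3 pairs, 0.253 to 0.378) and 0.271 between groups (12 pairs, 0.216 to 0.369), or 0.586 and 0.496 with the q limit and 0.563 and 0.46 with the strongest peaks.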

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

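The search for genes called in opposite directions was made only after the results were seen. It found 29 genes called one way in iWT and the other way in iTN against noDOX and called in the direct test, 18 of them higher in iWT and lower in iTN, and 8 of the 29 in a fixed list. Phox2a was at 2.77 in iWT and -2.61 in iTN, a difference of -5.38 (adjusted p = 4.63e-05). Slit1 was at 1.62 and -1.64, a difference of -3.26 (adjusted p = 2.76e-05). Neurod4 was at 1.60 and -1.63, a difference of -3.23 (adjusted p = 2.88e-06). St18 was at 1.36 and -1.24, a difference of -2.60 (adjusted p = 7.96e-05). Dll3 differed by -1.71 (adjusted p = 3.5e-05) and Hes6 by -1.23 (adjusted p = 2.46e-05). Rarb, a retinoic acid receptor gene, moved the other way, by 0.92 (adjusted p = 0.000201).

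The direct differences stayed called without any single library, as did both calls of Slit1 and Neurod4. Against noDOX, the iTN call of Phox2a was lost without iTN replicate 1 (adjusted p = 0.0588), 2 (0.0556) or 3 (0.0597) or noDOX replicate 3 (0.0643). The iTN call of St18 was lost without iTN replicate 2 (0.073) or 3 (0.0733) or noDOX replicate 1 (0.0877) or 3 (0.0862). The iWT call of Dll3 was lost without iWT replicate 1 (0.109) or 3 (0.166) or noDOX replicate 1 (0.0956) or 2 (0.128), and that of Hes6 without iWT replicate 1 (0.0932) or 3 (0.0631) or noDOX replicate 2 (0.0656). Rarb lost its iTN call whichever of the 6 libraries was left out, with adjusted p from 0.0791 to 0.189. Its iWT call was lost without iWT replicate 2 (0.0523) or 3 (0.0516) or noDOX replicate 1 (0.0666) or 2 (0.0558).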

How the results depend on the processing

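Settings for left-out libraries in lists, bound genes and peaks, for the most read sites, for bins of expression, for genes from the paired fit and for the human sets were chosen only after the results were seen. DESeq2 called 786 genes in iTN and 1720 in iSD against noDOX, 620 in iSD against iWT, 793 in iSD against iTN and 31 in human cells. A test against a 1.5-fold change called 317, 103 and 156 genes in iWT, iTN and iSD against noDOX, 351 in iTN against iWT, 29 in iSD against iWT, 57 in iSD against iTN and 7732 sites. With only the compared groups in the fit the counts were 441 (iSD against noDOX), 69 (iSD against iWT) and 176 (iSD against iTN). With the replicate block, which pairs the samples, they were 4989, 1718 and 3947 against noDOX, 4895, 1715 and 2216 for iTN and iSD against iWT and iSD against iTN, and 63 in human cells, where 2 pairs are too few to show pairing (correlation 0.437 within and -0.437 between numbers). In mouse RNA the block changed no other call given here. It ended the calls of the sites near Pax6 and Nkx2-2, whose libraries were not shown to pair. No count filter called 58 human genes. Of 84 list calls, 0 were kept with an estimated correlation. Fry called 55 lists, among them 41 of the mouse calls and 1 of the human calls. The human sets, with 0 calls as planned, gave 10 with the 200 smallest p, 10 with the replicate block and 7 with the libraries divided. Sites above the median count kept 5 of 8 bound gene calls. Odds ratios that lost their call were 1.16, 1.22 and 1.11 (lower in iSD), 1.09 and 1.10 (lower in iTN than in iWT), 1.69 (lower in iTN than in noDOX) and 1.15 (higher in iWT), and those on the other side of 1 were 0.983 for iSD with the paired fit and 0.896 for iWT with the 5000 most read sites.

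H3K27ac overlaps with the 20000 strongest peaks, with -log10 q of at least 5 and with reciprocal overlap were 64.6%, 55.2% and 38.7% (noDOX in iWT), 71.7%, 71.1% and 44.9% (noDOX in iTN), 78.6%, 95.9% and 37.6% (iWT in noDOX), 76.0%, 92.0% and 40.1% (iWT in iTN), 83.5%, 92.8% and 32.2% (iTN in noDOX) and 71.6%, 68.3% and 29.6% (iTN in iWT). Sites inside a peak were 8.37% and 4.0% with the strongest peaks and the q limit, against 17.7% over the 6 lists, 9.15% and 4.14% in iTN, 6.94% and 2.78% in iWT and 9.01% and 5.07% in noDOX. Without single libraries the counts ranged over 919 to 1833, 204 to 306 and 473 to 874 in iWT, iTN and iSD against noDOX. They were 791 to 1171 for iTN against iWT, 68 to 231 for iSD against iWT, 124 to 274 for iSD against iTN, 2 to 122 in human cells, 6369 to 14931 for sites and 72 to 90 for list calls. Overlaps ranged over 24.8 to 68.3% (noDOX in iWT), 31.3 to 80.6% (noDOX in iTN), 23.7 to 69.9% (iWT in noDOX), 30 to 76.3% (iWT in iTN), 15.7 to 55.7% (iTN in noDOX) and 15.2 to 53.6% (iTN in iWT), and bound gene calls over 7 to 8, with odds ratios of 1.22 to 1.57 for genes lower in iSD. An overlap of NKX2-2 regions by 50% and alternatives for normalized values were not run. No paired analysis was possible for the H3K27ac overlaps because each set merges both numbers. The cause was not tested.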

Other observations

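The tests of other splits and of NKX2-2 occupancy were fixed before the results, and those of transcript level, of the human pairs, of crossed and left-out libraries and of scaling were chosen only after the results were seen.

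Genes lower in iWT than in noDOX were less lowered in iTN, and Nkx2-2 transcripts were also lower in iTN than in iWT. If that level were the cause, iSD, whose Nkx2-2 differed from iTN by 0.12 (adjusted p = 0.845), should lie near iTN. The median log2 ratio of iSD over iTN for the 934 genes was -0.229, with 88.5% below 0, so the transcript level is unlikely to be the only cause. Protein level was not analysed here, and the line carrying each transgene remains a candidate explanation.

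The lists lower in human vpMN (3 neuronal and the pancreatic endocrine) could come from 1 pair of libraries. Their 68 members had a median log2 ratio of -1.19 (95% interval -1.63 to -0.881) in the pair numbered 2 and -1.39 (-1.66 to -1.02) in the other. Of them, 59 (86.8%) were lower in both. Both pairs were lower, but choosing the lists in these libraries favors this, so the question stays open. A larger share of differentiating cells in the pMN gate may also give this pattern and was not tested.

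Sites gained and lost NKX2-2 reads in iTN, perhaps from 1 library or scaling. With each library left out in turn (2 libraries against 1) at least 6369 sites were called against 15193 with all, so 1 library was not the whole cause. The smaller direction held at least 40.4% of calls over 5 other scalings, but all centre on the sites, so an overall shift stays open. Crossed groupings called 0 sites, where the group difference enters the spread, which decides nothing. Of genes with a site, 15.6% of those higher in iTN than in iWT and 10.8% of those not called had sites lost in iTN. The Mantel-Haenszel odds ratio by site count was 1.31 (95% interval 1.01 to 1.69). For sites gained these were 31.6%, 25.1% and 1.18 (0.964 to 1.44). Genes lower in iTN had lost sites more often (1.68, 1.31 to 2.15) and gained ones less often (14.5%, 0.459, 0.353 to 0.595). The role of occupancy stays open.

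The libraries of each mouse contrast were also divided in every other way into 3 and 3. Of 10 splits, 1 called as many genes as the real one in each of the 6 contrasts, the real one itself, so the share cannot be under 0.05. In fits of the compared groups alone, the real splits called 1612 genes for iWT against noDOX, 386 for iTN against noDOX, 441 for iSD against noDOX, 1604 for iTN against iWT, 69 for iSD against iWT and 176 for iSD against iTN. The highest other split called 0 in every contrast, the 3 others that part all 3 pairs of numbered libraries included.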
